A study of Mus musculus with 30 samples.

How the data were processed

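Inguinal mammary glands of mice on a 129sv background, 19 weeks old, were profiled on 2-colour Agilent arrays, with 1 array per gland. Gland RNA was labelled with Cy5 and hybridised together with Cy3-labelled universal mouse reference RNA from Stratagene, which is the same comparison sample on all 30 arrays. The values are deposited by the authors as the log2 ratio of gland over reference for each of 20896 probes. The base of the logarithm was inferred from the values, which stop at a size of 6, or 64-fold, and the direction of the ratio was taken from the dyes in the labels. The scanner settings, background correction, normalization within arrays, rule for blank values and probe filter of the authors are not stated. The array medians lay between -0.12 and -0.00. Each array held between 17485 and 20801 values, and no intensities are in the table, so the signal over background behind a value is unknown and the number of arrays limits the precision.

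Many values occur digit for digit more than once on the same array and are called repeated values here. Their number ran from 2639 to 10385 per array, and 75.0% of them lay within 0.3 of 0. The mean number per array was 6403 ± 1353 (SD, n = 7) in WT, 5022 ± 1807 (n = 8) in IFNAR1-/-, 7123 ± 3273 (n = 6) in Her2/Neu+ and 8054 ± 1500 (n = 9) in Her2/Neu+/IFNAR1-/- glands. How these values were made is not stated. They were kept, and alternatives without them were run after they had been seen.

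A probe was assigned to the gene symbol given for it by the array platform, with the chromosome and neighbouring genes taken from the RefSeq annotation of the mouse assembly GRCm38.p6. Of the probes, 17376 carried 1 symbol and 3520 carried none. A probe was kept if it had a value on at least 50% of the arrays of every group, which left 16247 named and 3278 unnamed probes. The values of all probes of a gene were averaged, which gave 11463 genes, 2606 of them with more than 1 probe. No further scaling was applied. Arrays are named by group and by the sample number in the labels.

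Differences were fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes without a trend, in 1 fit over the 30 arrays with a mean for each group. The contrasts were IFNAR1-/- minus WT, Her2/Neu+ minus WT, Her2/Neu+/IFNAR1-/- minus Her2/Neu+, Her2/Neu+/IFNAR1-/- minus IFNAR1-/-, and the interaction, which is the effect of receptor loss with the oncogene minus that without it. All tests were two-sided. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors of a change are standard errors (SE) from the fit. Because the labels number separate samples, the p-values measure the spread between these samples.

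A set of 22 gene lists was tested in each contrast with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list. Each was adjusted over the 110 tests, and fry was run beside it. Blank values, 2.87% of the gene by array values, were filled with the group mean for camera and fry only. The members of a list past the threshold were counted over all genes and also adjusted over the list alone. The mean of a list on each array, after centring each gene, was compared between groups by an exact permutation test, adjusted over 88 tests. Correlations of changes were computed across genes and set against 100 regroupings of the arrays.

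The genes named in each contrast are the 8 with the largest rise and the 8 with the largest fall among genes with an official symbol past the threshold, and up to 4 members with the smallest p of each list past it. For a list with no member past it, the member with the smallest p may be given as a value. Ifnar1, Ifnar2 and Erbb2 were always named, and Y-linked genes and Xist were left out. The comparisons, tests, lists, naming rule and a first set of alternatives were fixed before the data were examined. That set covered quantile normalization, median centring, filters on blank values and on low variation, the choice of probe, the groups in the fit, array weights, a variance trend, array position, slide, array set, a B cell covariate, a stricter threshold, a minimum change of 2-fold and leaving out each array. The 8 slides and the 2 array sets of 15 arrays were inferred from the block numbers and the order of the samples and are not stated in the labels. No inferred slide holds arrays of both groups of any pairwise contrast, so the p-values of these contrasts cannot tell groups from slides. Contrasts averaged over both backgrounds, cameraPR, the arrays of 1 set alone, the fit without the last slide and the alternatives on repeated values were added after the data had been seen.

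The fit was tested on simulated data in which 200 genes, and the interferon-stimulated list beside them, were changed in each contrast. Of the genes changed 2-fold, 33% were called in IFNAR1-/- minus WT, 10% in Her2/Neu+ minus WT, 28% in Her2/Neu+/IFNAR1-/- minus Her2/Neu+ and 24% in Her2/Neu+/IFNAR1-/- minus IFNAR1-/-. For genes changed 4-fold the shares were 76%, 75%, 71% and 74%. Every called changed gene had the right sign, and the data without added changes gave 0 calls in limma. Beside 109, 85, 99 and 98 changed genes, 8, 7, 4 and 10 unchanged genes were called in the same order of contrasts. That is 6.84%, 7.61%, 3.88% and 9.26% of these calls, above the nominal 5% in 3 of the 4 contrasts. The simulated values were drawn independently from normal distributions, without correlation between genes, slide effects, repeated values or the limit of the scale. These shares therefore do not give the error rate of the fit on the real arrays. Files were read with the data.table package, version 1.17.8, and plots were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.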

Results

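RNA from the inguinal mammary gland was measured in 4 groups of mice: 7 WT, 8 IFNAR1-/-, 6 Her2/Neu+ and 9 Her2/Neu+/IFNAR1-/-. IFNAR1 is a chain of the receptor for type I interferons, and Her2/Neu is an oncogene of the ERBB receptor family that drives mammary carcinomas in mice. The series asks what part the body's own type I interferon plays in carcinogenesis driven by this oncogene. Every value is a log2 ratio of the gland to the same reference RNA, so a negative value means a lower level than in the reference. Each array gave between 17485 and 20801 values, and the correlation between arrays ran from 0.345 to 0.858.

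Ifnar1, the targeted gene, had a mean log2 ratio of 0.42 ± 0.92 (SD, n = 7) in WT and 0.20 ± 0.89 (n = 8) in IFNAR1-/- glands. It was 0.77 ± 1.45 (n = 6) in Her2/Neu+ and 1.04 ± 1.23 (n = 8) in Her2/Neu+/IFNAR1-/- glands. The change with receptor loss was -0.23 ± 0.56 (SE) without the oncogene and 0.27 ± 0.58 with it, and neither passed the test (adjusted p = 0.961 and 0.880). The labels do not say whether the 2 probes lie in the deleted part, so these values check nothing about the genotypes. Ifnar2, the other receptor chain, stood at -0.04 ± 0.54 (n = 7), 0.10 ± 0.53 (n = 8), -0.39 ± 1.01 (n = 6) and -0.26 ± 0.46 (n = 9) in the same order of groups and passed in no contrast. Mouse Erbb2, read by 10 probes that may not detect the transgene, stood at 0.19 ± 0.39, 0.52 ± 0.63, 0.51 ± 0.40 and 0.38 ± 0.45 and passed in no contrast either. The 9 measured neighbours of Ifnar1 on its chromosome had a median change of -0.17 in IFNAR1-/- against WT (camera adjusted p = 0.909) and of 0.18 in Her2/Neu+/IFNAR1-/- against Her2/Neu+ (adjusted p = 0.521), with 0 members past the limma threshold in each and 1 up when adjusted over the list alone.

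Loss of the receptor in glands without the oncogene was compared first, which asks what interferon signalling contributes to the normal gland. Interferon-stimulated genes stood lower in IFNAR1-/- than in WT glands, with a median change of -0.56 over 31 of the 38 listed genes, a call by camera (adjusted p = 0.00176) that was lost with an estimated correlation (adjusted p = 0.709) and rests on no single member past the threshold. Glo1, which encodes the enzyme that detoxifies methylglyoxal, fell by 1.61 ± 0.28 on the log2 scale, or 3.06-fold, from 0.94 ± 0.27 (SD, n = 7) to -0.68 ± 0.36 (n = 8, adjusted p = 0.0113). Tbc1d2, a regulator of Rab GTPases, fell by 2.09 ± 0.36 on the log2 scale, or 4.27-fold, from 0.81 ± 0.58 to -1.28 ± 0.76 (adjusted p = 0.0113). For Glo1 and for Tbc1d2, all 8 IFNAR1-/- arrays lay below all 7 WT arrays. Both calls were lost with slide as a random block, where the changes were -1.61 ± 0.30 and -2.08 ± 0.40 with larger errors (adjusted p = 0.0511 for each). Glo1 was also lost after quantile normalization, at -1.51 ± 0.31 (adjusted p = 0.0957). With repeated values set to missing Tbc1d2 could not be tested, while Glo1 passed (adjusted p = 0.0135). The 1 gene that rose, Flywch2, went from 0.01 ± 0.07 (n = 5) to 2.74 ± 0.75 (n = 6, adjusted p = 0.000518), but all 5 of its WT values were repeated values, so the size of its rise was not measured. In all, 3 of 11463 genes passed, 1 up and 2 down, and 787 had an unadjusted p under 0.05.

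None of the 31 measured members of the interferon-stimulated list passed over all genes or adjusted over the list alone, 0 in limma by each count. Rtp4, the member with the smallest p, had a change of -2.06 ± 0.64 (adjusted p = 0.552). The mean of the list on each array was -0.88 ± 0.25 (SD, n = 8) in IFNAR1-/- and -0.27 ± 0.36 (n = 7) in WT glands, a difference of -0.61 (exact permutation p = 0.00140, adjusted p = 0.0495), and all 8 IFNAR1-/- arrays lay below the WT mean. The median change was -0.27 in array set 1, where the list was not called (adjusted p = 0.401), and -0.93 in array set 2.

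Markers of skeletal muscle, a tissue that can come along with the gland, were high on 3 of the 8 IFNAR1-/- arrays, 41, 42 and 44, with list means of 3.70, 3.93 and 4.10. The other 5 lay between -1.31 and -0.29, within the WT range of -1.45 to -0.07, so the rise is not shared by the group. The median change over 6 of 12 listed genes was 1.71 (camera adjusted p = 0.000134, adjusted p = 0.603 with an estimated correlation). Of these, 0 passed over all genes and 1 rose when adjusted over the list alone. Acta1, skeletal muscle actin, had a change of 3.28 ± 0.90 (adjusted p = 0.477). The array means of the muscle list differed by 1.69, within the spread between arrays (exact permutation p = 0.149). Extracellular matrix and mesenchymal genes had a median change of 0.35 over 15 genes (camera adjusted p = 0.0193, adjusted p = 0.603 with an estimated correlation), with 0 members past by either count. That call was lost without WT 60 (median 0.29, adjusted p = 0.0821), IFNAR1-/- 39 (0.28, adjusted p = 0.0507) or IFNAR1-/- 47 (0.33, adjusted p = 0.0546). It was also lost with the B cell covariate (0.26, adjusted p = 0.163), in array set 1 (0.47, adjusted p = 0.0598) and in array set 2 (0.04, adjusted p = 0.354). The T and NK cell list had a median of -0.46 (adjusted p = 0.190), the B cell list of -0.84 (adjusted p = 0.166) and the brown and beige fat list of -0.24 (adjusted p = 0.372), and none of these was called. The number of genes past the threshold was 5 without WT 60, 1 with slide as a random block, 5 in array set 1 alone and 0 in limma in array set 2 alone. Glo1, Tbc1d2 and Flywch2 passed in neither set alone (adjusted p = 0.380 or more).

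The oncogene in glands with an intact receptor was compared next, which asks how Her2/Neu changes the gland when interferon signalling is present. Lalba, which encodes the milk protein alpha-lactalbumin, and a group of interferon-induced antiviral genes stood far above WT in Her2/Neu+ glands. Lalba reached 5.93 ± 0.17 (SD, n = 6) in Her2/Neu+ glands, with 5 of 6 arrays at the limit of the scale, against 0.07 ± 0.12 (n = 4) in WT (adjusted p = 8.1e-06). All 4 of its WT values were repeated values, so its change of 5.86 ± 0.54 is no measured size. Among 2-5 oligoadenylate synthetase genes, which sense viral RNA, Oas1a rose by 3.24 ± 0.65, or 9.42-fold, from -1.78 ± 0.63 (n = 7) to 1.46 ± 1.47 (n = 6, adjusted p = 0.0268). Oasl2 rose by 3.30 ± 0.60, or 9.84-fold (adjusted p = 0.0130), and Oas1f by 3.89 ± 0.73, or 14.8-fold (adjusted p = 0.0158).

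Xbp1, a transcription factor of the secretory pathway, rose by 1.65 ± 0.27, or 3.13-fold, from 0.02 ± 0.29 to 1.66 ± 0.41 (adjusted p = 0.00466). Rises were also seen for Ier3, an immediate early gene, by 3.67 ± 0.67 (adjusted p = 0.0130), for Epha2, an ephrin receptor, by 3.41 ± 0.66 (adjusted p = 0.0191), and for Car12, a carbonic anhydrase, by 3.02 ± 0.58 (adjusted p = 0.0191). In each of Oas1a, Oasl2, Oas1f, Xbp1, Ier3, Epha2 and Car12, all 6 Her2/Neu+ arrays lay above all 7 WT arrays. Bglap2, an osteocalcin gene, rose by 3.34 ± 0.64 with 6 of 6 WT values repeated (adjusted p = 0.0226). Of the 2 genes that fell, Tsc22d3, a glucocorticoid-induced leucine zipper gene, fell by 1.87 ± 0.31 on the log2 scale, from 2.50 ± 0.50 to 0.63 ± 0.81 (adjusted p = 0.00466, below all WT arrays in 6 of 6). Fn1, fibronectin, fell by 1.93 ± 0.41 on the log2 scale, from -1.77 ± 0.84 to -3.70 ± 0.64 (adjusted p = 0.0402, below all WT arrays in 5 of 6). Apol9b, BC018473, Casp4 and Sdf2l1 rose as well, by 2.80, 2.98, 1.86 and 2.04, and are named after their values were seen.

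In all, 15 genes passed between Her2/Neu+ and WT, 13 up and 2 down, while 1383 had an unadjusted p under 0.05, 616 of them up and 767 down. The split moved with the processing and the arrays used: it was 15 up and 9 down after quantile normalization, 22 and 16 with repeated values missing, 12 and 26 for probes repeated on at most 3 arrays, and 209 and 536 in array set 2 alone. Of the 15, 4 had repeated values on at least 50% of the arrays of a compared group, among them Car12 with 5 of 7 in WT. With repeated values set to missing Lalba, Bglap2 and Car12 could not be tested, and the other 8 named genes passed. The count was 132 without Her2/Neu+ 115, 23 without Her2/Neu+ 114, 3 without Her2/Neu+ 118, 8 without Her2/Neu+ 119 and 6 without Her2/Neu+ 120, and 7, 9, 8 and 9 without WT 54, 56, 57 and 60. Lalba, Tsc22d3 and Xbp1 passed in all 30 fits that left out 1 array. The calls of Oas1f, Ier3, Epha2, Bglap2, Oasl2, Oas1a, Car12 and Fn1 were all lost without Her2/Neu+ 118, and some of them without Her2/Neu+ 114, 119 or 120, WT 53, 54, 56, 57, 59 or 60, or, for Fn1 alone, IFNAR1-/- 42, 45, 46, 47 or 50 and Her2/Neu+/IFNAR1-/- 105 or 106. The highest adjusted p so reached was 0.0753 for Oas1f, Ier3, Epha2, Bglap2 and Oasl2, 0.0763 for Car12, 0.131 for Fn1 and 0.133 for Oas1a. Fn1 was lost as well after quantile normalization (-1.70, adjusted p = 0.0633) and without the last slide (-1.56, adjusted p = 0.106). With only the compared groups in the fit Bglap2, Car12, Fn1 and Tsc22d3 were lost (adjusted p = 0.0558 to 0.127). With slide as a random block 3 genes passed: Lalba, Tsc22d3 and Xbp1. The other 8 named genes, the antiviral Oas1a, Oasl2 and Oas1f among them, were lost (adjusted p = 0.111 to 0.163). The count was 1 in array set 1 alone and 745 in array set 2 alone, where only 2 arrays are Her2/Neu+.

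As a group, interferon-stimulated genes had a median change of 1.15 in Her2/Neu+ glands (camera adjusted p = 2.5e-14, adjusted p = 0.603 with an estimated correlation). Over all genes 2 of 31 rose, Oas1a and Oasl2, and adjusted over the list alone 14 rose and 1 fell. The list mean was 0.99 ± 0.89 (SD, n = 6) against -0.27 ± 0.36 (n = 7), a difference of 1.27 (exact permutation p = 0.00641, adjusted p = 0.0940), with 6 of 6 arrays above the WT mean and 4 above all WT arrays. Its median change was 1.32 in array set 1 and 0.40 in array set 2, where the list was not called (adjusted p = 0.317). ERBB receptor and ERK target genes had a median of 0.53 over 9 of 14 genes (camera adjusted p = 0.0185, adjusted p = 0.603 with an estimated correlation), with 0 past over all genes and 1 up adjusted over the list alone. Etv5, an ETS factor downstream of ERK, had a change of 2.12 ± 0.63 (adjusted p = 0.158). The ERBB and ERK call was lost without Her2/Neu+ 118 (median 0.51, adjusted p = 0.0723) or Her2/Neu+ 113 (0.57, adjusted p = 0.0524). It was also lost with probes that had a value on all arrays (0.33, adjusted p = 0.0721), with the probe of largest SD (0.84, adjusted p = 0.0752) and in array set 2 (0.27, adjusted p = 0.799). The median was 1.22 with repeated values missing (camera adjusted p = 0.0028), a fit that kept fewer probes, so this is no like-for-like comparison. It was 0.83 without the last slide (camera adjusted p = 0.0017), so its size moved with the processing and the arrays used.

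Cell cycle genes had a median change of 0.64 over 22 of 25 genes (camera adjusted p = 0.00181, adjusted p = 0.603 with an estimated correlation), with 0 past by either count. Without Her2/Neu+ 114 the cell cycle median was 0.22 (adjusted p = 0.103), without the last slide it was 0.31 (adjusted p = 0.172), and with repeated values missing it was 0.52 (adjusted p = 0.0749). Extracellular matrix and mesenchymal genes had a median of -0.46 (camera adjusted p = 0.00775, adjusted p = 0.603 with an estimated correlation), with Fn1 down over all genes and 4 down adjusted over the list alone. That median was -0.24 without Her2/Neu+ 118 (adjusted p = 0.0985), -0.30 without Her2/Neu+ 120 and -0.69 without Her2/Neu+ 119, and the call was lost in each array set alone (adjusted p = 0.129 and 0.237). Lists that were not called include basal and myoepithelial markers (median -0.81, adjusted p = 0.0517), antigen presentation by MHC class I (0.33, adjusted p = 0.0682), adipocyte markers (-0.21, adjusted p = 0.0656), endothelial markers (-0.60, adjusted p = 0.199), fatty acid synthesis (-0.40, adjusted p = 0.385), luminal epithelial markers (0.36, adjusted p = 0.527), macrophage markers (0.26, adjusted p = 0.773) and skin keratinocyte markers (0.52 over 2 genes, adjusted p = 0.521). The plasma cell list, which holds Xbp1, had a median of 0.38 (adjusted p = 0.0656) and 1 member up by both counts.

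**Figure D1:**
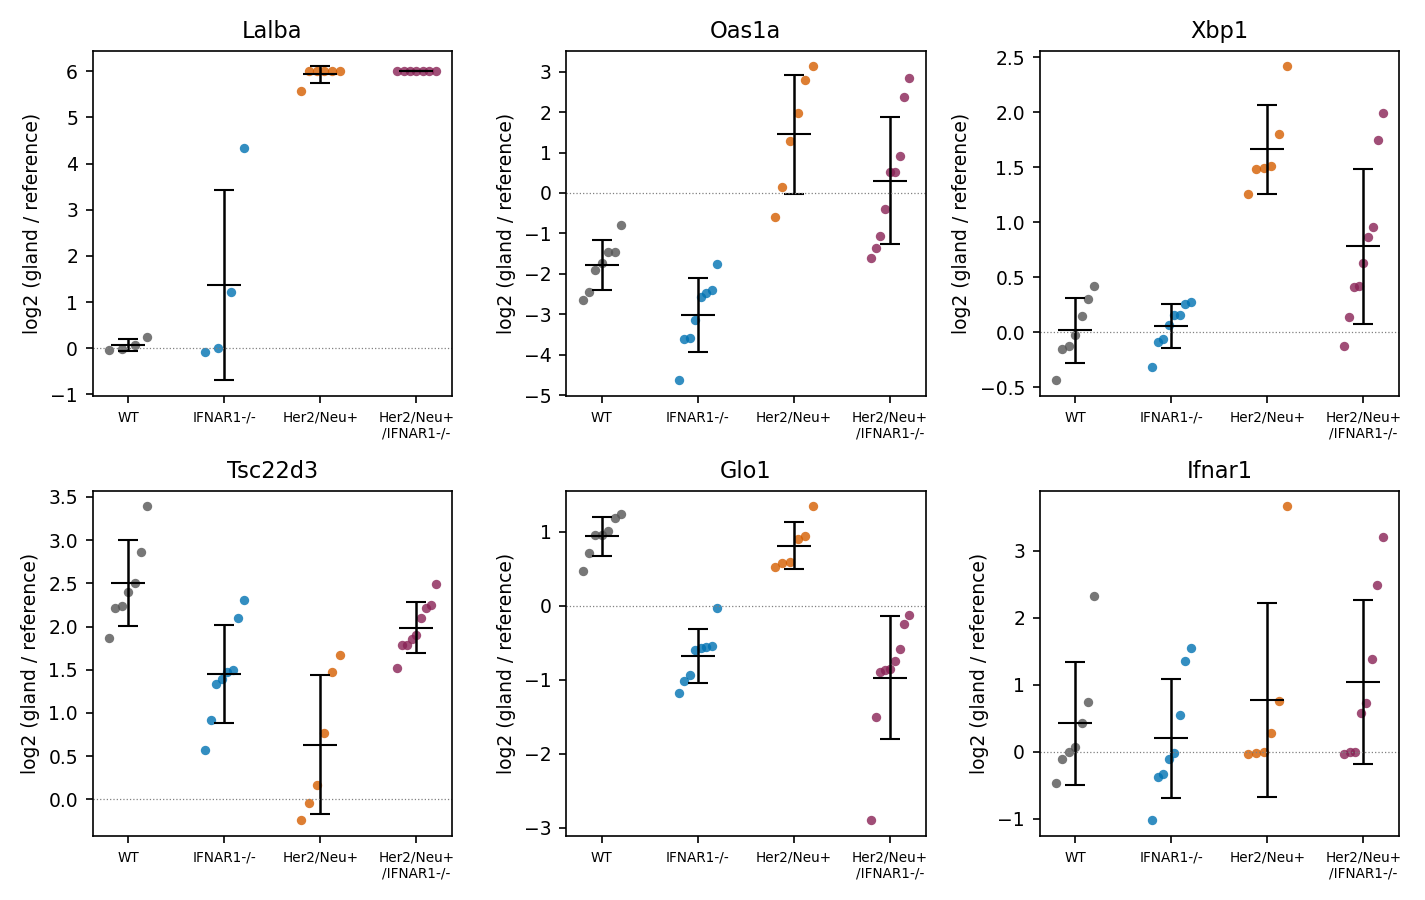
Log2 ratio of gland to reference RNA on each array for Lalba, Oas1a, Xbp1, Tsc22d3, Glo1 and Ifnar1 in the 4 groups, with points for single arrays and bars for the mean ± SD. Glo1 is lower in both groups without the receptor, Oas1a and Lalba are higher in both groups with the oncogene, and Ifnar1 overlaps between all groups.

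Loss of the receptor in glands with the oncogene was compared to ask what interferon signalling contributes once Her2/Neu is present. Glo1 was again lower without the receptor, by 3.45-fold: it fell by 1.78 ± 0.29 on the log2 scale, from 0.82 ± 0.31 (SD, n = 6) to -0.97 ± 0.83 (n = 9, adjusted p = 0.00173), and all 9 Her2/Neu+/IFNAR1-/- arrays lay below all 6 Her2/Neu+ arrays. Agpat2, an enzyme of triglyceride synthesis, rose by 2.84 ± 0.53, from 1.71 ± 1.82 to 4.55 ± 0.97 (adjusted p = 0.0155). Rnase4, a secreted ribonuclease, rose by 1.44 ± 0.28, from 0.83 ± 0.86 to 2.28 ± 0.53 (adjusted p = 0.0284). Clec3b, which encodes the plasma protein tetranectin, stood at the limit of the scale on 7 of 8 Her2/Neu+/IFNAR1-/- arrays, against 2.81 ± 2.07 (n = 4) in Her2/Neu+ (adjusted p = 0.0493), so the size of its rise was not measured. For Agpat2, Rnase4 and Clec3b every array without the receptor lay above the Her2/Neu+ mean, 9 of 9, 9 of 9 and 8 of 8. The other 5 genes that rose carry predicted-gene names and are named after their values were seen: Gm14288 by 1.75, Gm14326 by 1.69, Gm14391 by 1.77, Gm14393 by 2.63 and Gm14411 by 2.36.

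In all, 9 genes passed between these groups, 8 up and 1 down, and 1280 had an unadjusted p under 0.05. The count was 24 without Her2/Neu+ 113 and 18 without Her2/Neu+ 115, and it was 5 with slide as a random block, 2 in array set 1 alone and 903 in array set 2 alone. Glo1 passed in all 30 fits that left out 1 array, while Agpat2 was lost without Her2/Neu+ 114 or 119 (adjusted p up to 0.0701) and Rnase4 without those or Her2/Neu+/IFNAR1-/- 104, 106, sample107, 108 or 109 (up to 0.0952). Clec3b passed in 8 of 30 fits, those without Her2/Neu+ 113, 114, 115 or 120, IFNAR1-/- 42, WT 55 or Her2/Neu+/IFNAR1-/- 102 or 110, and each other array ended its call (adjusted p up to 0.193). Agpat2, Rnase4 and Clec3b were also lost in 6 of the alternatives that changed the processing or the fit. Their adjusted p, in that order, was 0.0701, 0.126 and 0.0701 after quantile normalization, 0.0994, 0.111 and 0.0862 with repeated values missing, and 0.0613, 0.0668 and 0.119 with slide as a random block. It was 0.220, 0.267 and 0.220 without the last slide and 0.158, 0.237 and 0.352 with array weights. Rnase4 or Clec3b was lost in a few further alternatives (adjusted p = 0.0505 to 0.0684). Without the last slide the changes were 2.13 for Agpat2 and 0.93 for Rnase4. With only the compared groups in the fit, none of the 4 named genes passed, and Glo1 was at -1.78 ± 0.35 (adjusted p = 0.209).

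Interferon-stimulated genes had a median change of -0.68 in Her2/Neu+/IFNAR1-/- against Her2/Neu+ glands (camera adjusted p = 1.4e-07, adjusted p = 0.603 with an estimated correlation). By limma 0 of 31 members passed over all genes and 0 adjusted over the list alone, and Oasl1 had the smallest p, with a change of -1.65 ± 0.51 (adjusted p = 0.236). The list mean was 0.33 ± 0.84 (SD, n = 9) against 0.99 ± 0.89 (n = 6), a difference within the spread between arrays (exact permutation p = 0.166). Its median change was -0.95 in array set 1 and -0.27 in array set 2, where the list was not called (adjusted p = 0.668). Extracellular matrix and mesenchymal genes had a median of 0.53 (camera adjusted p = 0.00973, adjusted p = 0.603 with an estimated correlation), with 0 members past over all genes and 2 up adjusted over the list alone. Without Her2/Neu+ 118 that median was 0.25 (adjusted p = 0.0985), and in array set 2 it was 0.13 (adjusted p = 0.442). The cell cycle list had a median of -0.43 (adjusted p = 0.0502) and the MHC class II list of 0.38 (adjusted p = 0.935), and neither was called.

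The oncogene in glands without the receptor was compared last, which asks how much of the response to Her2/Neu is seen when type I interferon cannot signal. Interferon-stimulated genes were higher in Her2/Neu+/IFNAR1-/- than in IFNAR1-/- glands, with a median change of 1.02 and 7 of 31 members past the threshold, though the list was not called with an estimated correlation (adjusted p = 0.603). Oas1a rose by 3.33 ± 0.57, from -3.02 ± 0.91 (SD, n = 8) to 0.31 ± 1.58 (n = 9, adjusted p = 0.00460), and all 9 arrays with the oncogene lay above all 8 without it. Rtp4 rose by 3.06, or 8.36-fold (adjusted p = 0.0114), Usp18, a brake on interferon signalling, by 2.75, or 6.72-fold (adjusted p = 0.0258), and Oasl2 by 2.70, or 6.51-fold (adjusted p = 0.0112). Each of these 3 genes was above the IFNAR1-/- mean in 9 of 9 arrays, and each was lost with slide as a random block (adjusted p = 0.0664, 0.128 and 0.0664).

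Several genes outside the interferon list rose too. Car12 rose by 3.42 ± 0.51, from -2.06 ± 0.82 to 1.36 ± 1.28 (adjusted p = 0.000794, above all IFNAR1-/- arrays in 9 of 9). Car6, a secreted carbonic anhydrase, rose by 3.61 ± 0.61 (adjusted p = 0.00460), Oas1f by 3.22 (adjusted p = 0.0118), Ier3 by 3.15 (adjusted p = 0.00725) and Bglap2 by 3.23 (adjusted p = 0.00701). Lalba stood at the limit of the scale on all 7 Her2/Neu+/IFNAR1-/- arrays with a value, against 1.36 ± 2.06 (n = 4) in IFNAR1-/- glands (adjusted p = 0.000197). Mcm2, a subunit of the replicative helicase, rose by 1.78 (adjusted p = 0.0424), and Dusp6, a phosphatase that limits ERK, by 1.38 (adjusted p = 0.0303), each above the IFNAR1-/- mean in 9 of 9 arrays.

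Among the falls, Pltp, a lipid transfer protein gene, fell by 1.90 on the log2 scale, from 2.21 ± 0.85 to 0.31 ± 0.73 (adjusted p = 0.00651, below all IFNAR1-/- arrays in 8 of 9). Psmb7, a proteasome subunit gene, fell by 1.66 on the log2 scale (adjusted p = 0.0267), and Aox1, aldehyde oxidase, fell by 2.14 on the log2 scale (adjusted p = 0.0434). Krt14, a keratin of basal cells, fell by 2.47 (adjusted p = 0.0413), Rtl8a fell by 1.76 (adjusted p = 0.0447), Slc22a23 fell by 2.05 (adjusted p = 0.0353), Mustn1 fell by 2.18 (adjusted p = 0.0364) and Flywch2 fell by 2.78 (adjusted p = 0.000197). In Krt14, Slc22a23, Mustn1 and Flywch2 all values of the Her2/Neu+/IFNAR1-/- group were repeated values, so the sizes of these falls were not measured. With repeated values set to missing only 8 of the 20 named genes could be tested, and these 8 passed. Lalba, Bglap2, Pltp, Aox1, Rtl8a, Car6, Car12 and Mcm2 were not among them, so their changes could not be checked without repeated values. Of all genes past the threshold, 45 had repeated values on at least 50% of the arrays of a compared group.

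In all, 150 genes passed between Her2/Neu+/IFNAR1-/- and IFNAR1-/- glands, 108 up and 42 down, and 2121 had an unadjusted p under 0.05. The median change of all genes was 0.15 as deposited and 0.04 after quantile normalization, after which 41 genes rose and 67 fell, so the excess of rises turned with the scaling. The count was 58, 247, 46, 38 and 43 without Her2/Neu+/IFNAR1-/- 105, 106, 108, 109 and 110, it was 70, 325, 40, 43, 35 and 65 without IFNAR1-/- 39, 42, 44, 46, 47 and 50, and it was 95 and 93 without WT 56 and 57. With slide as a random block 13 genes passed, and 50 with array position, 2 in array set 1 alone and 6 in array set 2 alone. Lalba, Car6, Car12, Oas1a, Bglap2, Oas1f, Ier3, Rtp4, Flywch2, Pltp and Oasl2 passed in all 30 fits that left out 1 array. The other 9 named genes were lost without 1 or more of IFNAR1-/- 39, 41, 42, 44, 45, 46, 47 and 50, Her2/Neu+/IFNAR1-/- 102, 103, 104, 105, sample107, 108, 109 and 110, and WT 53, 55, 56, 57 and 59. The adjusted p so reached was at most 0.0605 for Psmb7 and Usp18, 0.0581 for Dusp6, 0.109 for Mcm2, 0.0956 for Krt14, 0.0957 for Mustn1, 0.0883 for Aox1, 0.0756 for Slc22a23 and 0.115 for Rtl8a, and the change of Mustn1 was -1.30 without IFNAR1-/- 50. With slide as a random block 7 of the 20 named genes passed: Lalba, Car6, Car12, Oas1a, Bglap2, Flywch2 and Pltp. The other 13 were lost. Among those lost were the interferon-induced Rtp4 and Oasl2 (adjusted p = 0.0664 for both), Oas1f (adjusted p = 0.0880) and Usp18 (adjusted p = 0.128). Ier3 was lost as well (adjusted p = 0.0594). With only the compared groups in the fit 11 of the 20 were lost (adjusted p = 0.0503 to 0.130), and with array position 7 (0.0551 to 0.0850). With the B cell covariate 4 (0.0533 to 0.0651) were lost, and with the array set factor 2 (0.0595 and 0.0692). Quantile normalization ended the calls of Mcm2 (1.34, adjusted p = 0.102) and Dusp6 (1.21, adjusted p = 0.0670), and leaving out the last slide that of Rtl8a (adjusted p = 0.0527).

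The interferon-stimulated list was called by camera at the preset correlation alone (adjusted p = 2.0e-07). Of its 31 members 7 rose over all genes and 13 adjusted over the list alone, and none fell by either count, 0 in limma. The list mean was 0.33 ± 0.84 (SD, n = 9) against -0.88 ± 0.25 (n = 8), a difference of 1.21 (exact permutation p = 0.000165, adjusted p = 0.0145), and all 9 arrays with the oncogene lay above all 8 without it. The median change was 1.05 in array set 1, 1.18 in array set 2 and 0.65 without Her2/Neu+/IFNAR1-/- 110 (adjusted p = 1.5e-05). Milk protein and secretory genes had a median of 0.41 over 7 of 13 genes (camera adjusted p = 0.0490, adjusted p = 0.603 with an estimated correlation), with Lalba up over all genes and 3 up adjusted over the list alone. Their list mean differed by 0.70 (exact permutation p = 0.00169, adjusted p = 0.0495), with 8 of 9 arrays above all IFNAR1-/- arrays. The call of the milk list was lost in 16 of 30 fits, those without IFNAR1-/- 39, 41, 42 or 45, WT 59 or 60, Her2/Neu+ 118, 119 or 120, or Her2/Neu+/IFNAR1-/- 102, 104, 105, 106, sample107, 108 or 109 (adjusted p up to 0.0823). It was also lost after quantile normalization, where the median was 0.13 (adjusted p = 0.111), and with repeated values missing, where it was 0.26 (adjusted p = 0.723). The size of this rise thus moved with the processing. Median centring (0.37, adjusted p = 0.0539) and probes with a value on all arrays (0.51, adjusted p = 0.216) ended the call too. So did probes repeated on at most 3 arrays (0.26, adjusted p = 0.356), leaving out the last slide (0.42, adjusted p = 0.0936) and array set 1 alone (0.48, adjusted p = 0.0843).

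Basal and myoepithelial markers had a median change of -0.73 over 8 of 10 genes (camera adjusted p = 0.0449, adjusted p = 0.603 with an estimated correlation), with Krt14 down over all genes, and 1 up and 1 down adjusted over the list alone. Extracellular matrix and mesenchymal genes had a median of -0.32 (camera adjusted p = 0.0299, adjusted p = 0.603 with an estimated correlation), with 0 past by either count. The basal call was lost without IFNAR1-/- 39, 45, 46, 47 or 50, Her2/Neu+ 113 or 118, or Her2/Neu+/IFNAR1-/- 102, 103, sample107 or 110 (adjusted p up to 0.124). It was also lost after quantile normalization (-0.80, adjusted p = 0.0717), after median centring (adjusted p = 0.0539), with array position (adjusted p = 0.0711), with slide as a random block (adjusted p = 0.0555) and with the B cell covariate (adjusted p = 0.0783). Probes that had a value on all arrays ended it (adjusted p = 0.448). It was not called with repeated values missing (-0.52, adjusted p = 0.503), with probes repeated on at most 3 arrays (-0.62, adjusted p = 0.634) and in array set 2 (-0.32, adjusted p = 0.370). The matrix call was lost without IFNAR1-/- 39 or 47, Her2/Neu+ 118, or Her2/Neu+/IFNAR1-/- 102, 106 or 110 (adjusted p up to 0.0660), and its median was -0.56 without IFNAR1-/- 42 and -0.55 without Her2/Neu+/IFNAR1-/- 103. It was also lost without the 25% of genes with the lowest SD (adjusted p = 0.0830), with the B cell covariate (adjusted p = 0.0938) and in array set 1 (-0.23, adjusted p = 0.428). Its median was -0.49 after quantile normalization and -0.66 with repeated values missing. ERBB receptor and ERK target genes had a median of 0.58 (camera adjusted p = 0.0562), with Dusp6 up over all genes and 5 up adjusted over the list alone. The cell cycle list had a median of 0.16 (adjusted p = 0.360), with Mcm2 up over all genes and 8 up adjusted over the list alone. The stem and progenitor list had a median of 0.25 (adjusted p = 0.498) and the immediate early list, which holds Ier3, of 0.60 (adjusted p = 0.189), and neither was called.

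**Figure D2:**
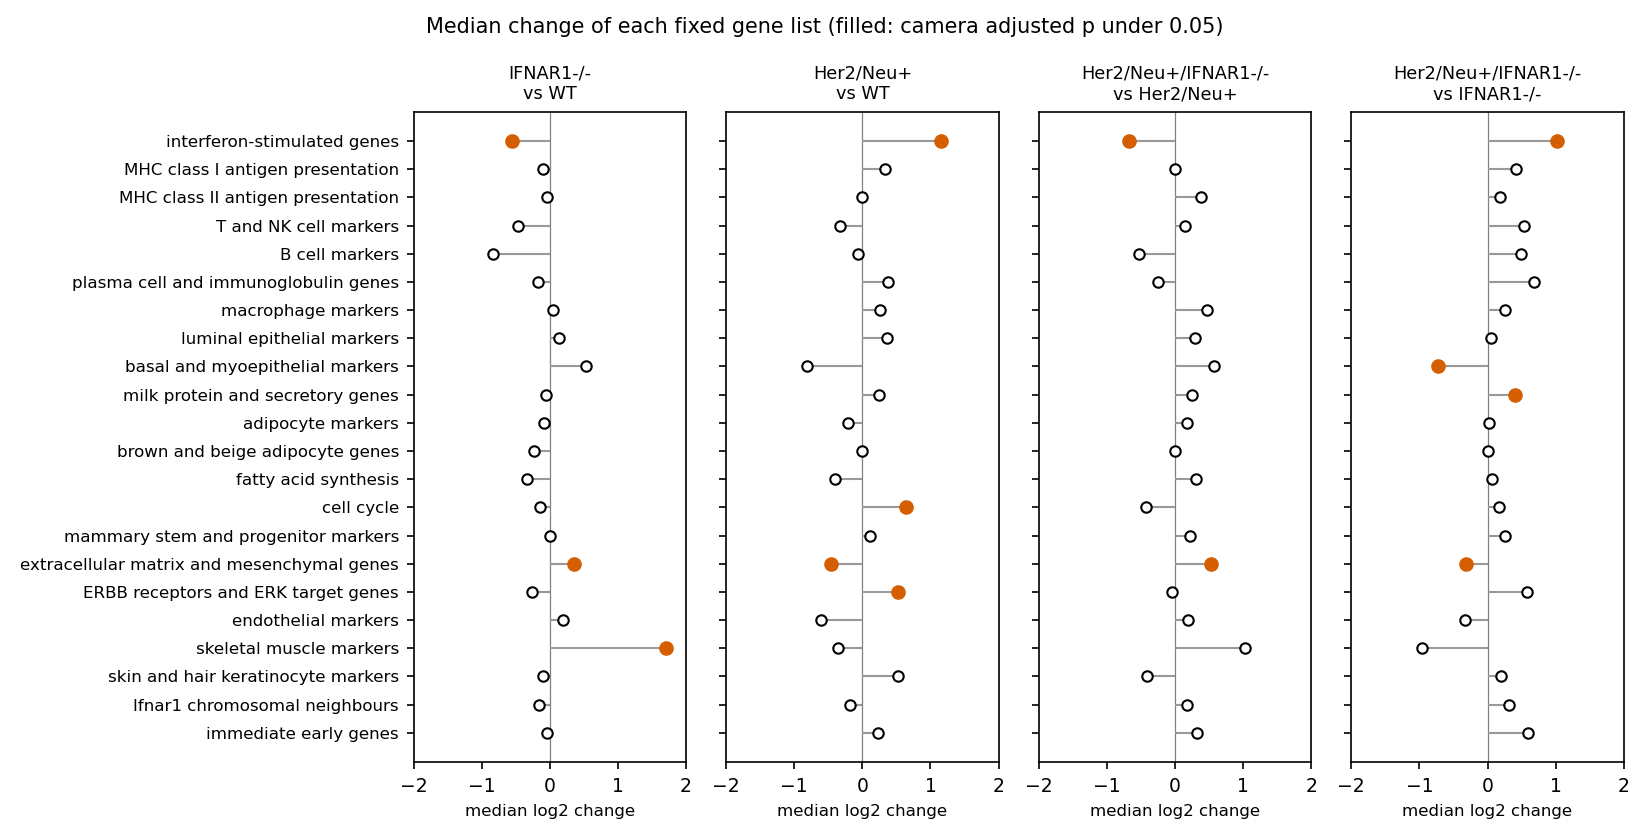
Median log2 change of each of the 22 gene lists in the 4 comparisons between groups, with filled orange points for lists past a camera adjusted p of 0.05 at the preset correlation. The interferon-stimulated list lies at -0.56 and -0.68 with loss of the receptor and at 1.15 and 1.02 with the oncogene.

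**Figure D3:**
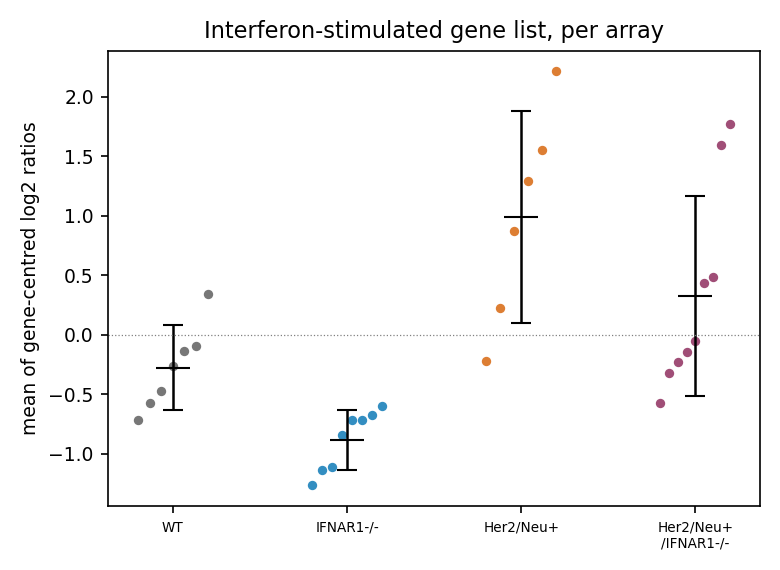
Mean of the gene-centred log2 ratios of the interferon-stimulated list on each array, with points for single arrays and bars for the mean ± SD of each group. The 8 IFNAR1-/- arrays have the lowest mean at -0.88 ± 0.25, and the 9 Her2/Neu+/IFNAR1-/- arrays all lie above them at 0.33 ± 0.84.

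The interaction asks whether loss of the receptor acts differently with and without the oncogene. Tsc22d3 passed with a difference of 2.41 ± 0.41 (SE, adjusted p = 0.0230): it stood at 2.50 ± 0.50 (SD, n = 7) in WT, 1.45 ± 0.56 (n = 8) in IFNAR1-/-, 0.63 ± 0.81 (n = 6) in Her2/Neu+ and 1.99 ± 0.30 (n = 9) in Her2/Neu+/IFNAR1-/- glands. Flywch2 passed with a difference of -3.06 ± 0.48 (adjusted p = 0.0282) and had a mean above 1 in IFNAR1-/- glands only, with repeated values in all WT and Her2/Neu+/IFNAR1-/- arrays that gave a value, so the size of its difference was not measured. Interferon-stimulated genes had a median difference of -0.23 (adjusted p = 0.189), so a different effect of receptor loss on them with the oncogene was not shown. In all 2 genes passed and 1103 had an unadjusted p under 0.05, with a median of all genes of 0.18 as deposited and 0.05 after quantile normalization. By limma the count was 0 without Her2/Neu+ 119, IFNAR1-/- 44 or WT 56, where Tsc22d3 was lost (adjusted p up to 0.0600). It was 3 without Her2/Neu+ 114, and 1 without Her2/Neu+/IFNAR1-/- 104, 105, 106, sample107 or 108, IFNAR1-/- 41, 46 or 50, or WT 54, 57, 59 or 60, where Flywch2 was lost, as it was without Her2/Neu+ 120 (adjusted p up to 0.141). Flywch2 was also lost with the array set factor (adjusted p = 0.206) and the B cell covariate (adjusted p = 0.0517), and Tsc22d3 with repeated values missing (2.02, adjusted p = 0.0712). Without the last slide 1 gene passed, but neither Tsc22d3 nor Flywch2 did (adjusted p = 0.173 and 0.170). Both were lost as well with slide as a random block (adjusted p = 0.100 for both), with array weights, a variance trend or array position, and without the 25% of genes with the lowest SD (adjusted p = 0.0539 to 0.106). By limma 0 genes passed with slide as a random block or in array set 1 alone, and 494 passed in array set 2 alone.

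Across genes, which are not independent replicates, the effect of receptor loss without the oncogene showed no relation to that with it (Pearson's r -0.0153, Spearman's rho -0.0258), and 48.1% of the genes moved the same way. The effects of the oncogene in the 2 receptor states had an r of 0.263 (rho 0.225), with 56.5% of the genes moving the same way. That r lies just above 0.253, the chance limit from regroupings of the 30 arrays in the reported fit. Limits for the other fits were not computed, so values under 0.253 in them are given as sizes and not as tests. The r was 0.241 with the probe of largest SD, 0.212 with array weights, 0.247 with the B cell covariate, 0.186 without the last slide, 0.156 in array set 1 alone and 0.148 in array set 2 alone. It was also under this limit, before rounding, without WT 56 (0.253), 57 (0.252) or 60 (0.213), IFNAR1-/- 39 or 42 (0.252 each), or Her2/Neu+ 113 (0.194), 114 (0.241), 115 (0.251) or 119 (0.249). So it was without Her2/Neu+/IFNAR1-/- 105 (0.225), 108 (0.242), 109 (0.253) or 110 (0.235). Glo1 fell in both comparisons of receptor loss. Of the 13 genes that rose with the oncogene when the receptor was present, 10 also rose when it was absent (0.122 expected if the lists were independent): Apol9b, Bglap2, Car12, Casp4, Ier3, Lalba, Oas1a, Oas1f, Oasl2 and Sdf2l1. Both comparisons use the same spread per gene from 1 fit, and genes are not independent, so 0.122 is not a chance level.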

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

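The tests of repeated values and of receptor-intact glands for the interferon-stimulated genes, the test of a segment around Ifnar1 and the regroupings behind the correlations were chosen after the results had been seen, as were the contrasts averaged over both backgrounds and the alternatives on repeated values, last slide and array sets.

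Interferon-stimulated genes were higher in Her2/Neu+/IFNAR1-/- than in IFNAR1-/- glands, although both groups are labelled as lacking the receptor for type I interferon. The list call was lost with an estimated correlation (adjusted p = 0.603), and its median of 1.02 was 0.65 without Her2/Neu+/IFNAR1-/- 110. With the T and NK cell, B cell and macrophage list means as covariates the median change was 1.17 (camera adjusted p = 5.3e-08), against 1.02. This argues against more immune cells of these types as the whole cause. With repeated values set to missing the median change was 1.48 (camera adjusted p = 2.4e-11). That fit kept 6454 genes in place of 11463, and fewer probes of some genes. The medians 1.48 and 1.02 are therefore not over the same probes. The rise remained among the probes kept there, which argues against repeated values as the whole cause for those probes alone. Whether receptor-intact glands are among the 9 stays open, since the genes called between IFNAR1-/- and WT disagree. By the midpoint between the WT and IFNAR1-/- means, Glo1 put 0 of the 9 Her2/Neu+/IFNAR1-/- arrays on the WT side, Tbc1d2 put 4 of 9 there (103, 108, 109 and 110), and Flywch2 put all 5 with a value there, all of them repeated values. The 6 Her2/Neu+ arrays lay on the WT side for Glo1 and for Tbc1d2. The mean of the interferon-stimulated list ran from -0.72 to 0.34 on the WT arrays. Her2/Neu+/IFNAR1-/- 105, 108, 109 and 110 lay above that range (1.60, 0.43, 0.48 and 1.77). The other arrays of that group lay within it, from -0.57 to -0.05, though above all IFNAR1-/- arrays. Of the arrays above the WT range, Tbc1d2 put 108, 109 and 110 on the WT side but not 105. The call of Glo1 between IFNAR1-/- and WT is itself lost after quantile normalization (-1.51, adjusted p = 0.0957) and with slide as a random block (-1.61, adjusted p = 0.0511). Induction by other routes, such as type II or type III interferon, was not tested and stays a hypothesis.

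Averaged over both backgrounds, 8 genes followed the loss of the receptor: Glo1 (-1.70) and Tbc1d2 (-1.41) were lower, and Rnase4 (1.33), Gm14288 (1.19), Gm14326 (1.10), Gm14391 (1.32), Gm14393 (1.65) and Gm14411 (1.54) were higher. With slide as a random block 7 of the 8 passed and Gm14391 was lost (adjusted p = 0.0791). Of the 8, 0 lie on the chromosome of Ifnar1 and 0 are among its 9 measured neighbours by limma, where 988 genes had an unadjusted p under 0.05, which argues against a segment carried along with the deletion. The 5 Gm genes had a median within-group correlation of 0.455, above 99.98% of 10000 random sets of 5 genes (95th percentile 0.183), so they may be probes of 1 gene family that read the same transcripts, and they count as 1 observation rather than 5. They also lie close together, with 10 pairs within 25 tested genes of each other and 0 of 10000 random sets with as many. A difference in genetic background between the receptor-null and receptor-intact mice outside the Ifnar1 segment stays open and was not tested.

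Other splits of the same arrays into groups of the same sizes were counted, 100 for each comparison with the real one included. The smallest share that 100 splits can give is 1 of 100, so they do not exclude chance. For arrays that vary independently of their slide, chance is unlikely where 1 of 100 splits, the real one, gave as many genes. This held for IFNAR1-/- against WT (3 genes, highest other split 1), Her2/Neu+ against WT (15, highest other 2) and Her2/Neu+/IFNAR1-/- against IFNAR1-/- (150, highest other 38). It also held for the averages over receptor loss (8, highest other 3) and over the oncogene (295, highest other 3). For the interaction, too, 1 of 100 splits, the real one, gave as many genes (2, highest other 1). These splits mix all 4 groups and so remove the effects of the oncogene and of receptor loss as well. They therefore cannot exclude chance for the interaction itself. The splits move single arrays, but no inferred slide holds arrays of both groups of any pairwise comparison. With slide as a random block the counts of the 3 comparisons fell in the same order to 1, 3 and 13, and those of the averages to 7 and 73. By limma the interaction count fell to 0 (1103 had an unadjusted p under 0.05 without the block). The block uses 1 correlation, 0.0951, for all genes and does not remove shifts of single genes between slides. For genes lost and genes kept alike, a difference between slides and one between groups thus cannot be told apart in the pairwise comparisons. In the averages and the interaction they cannot be fully told apart. Both interaction genes were among those lost (adjusted p = 0.100 for each). For Her2/Neu+/IFNAR1-/- against Her2/Neu+, 5 of 100 splits gave as many as the real 9 genes, so chance cannot be excluded for that count. The highest other split gave 89, and what set that split apart was not examined. For the correlations across genes, 88 of 101 groupings gave a receptor correlation as far from 0 as the real -0.0153 (highest other 0.221), so chance cannot be excluded. For the oncogene 4 of 101 gave one as far from 0 as the real 0.263 (highest other -0.352), a share just under 0.05. These regroupings also move single arrays and ignore the slides. For arrays that vary independently of their slide, chance is thus unlikely for the correlation as reported but not excluded. It was lower without the last slide (0.186), with array weights (0.212), with the B cell covariate (0.247), with the probe of largest SD (0.241), in array sets 1 and 2 alone (0.156 and 0.148) and in fits that left out 1 array (lowest 0.194, without Her2/Neu+ 113). Regroupings were not run for these fits, so the share of 4 of 101 holds for the reported fit alone.

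An array was singled out when its gap to the nearest array of its group was large against the range of the group. This held for 22 of 231 groups of values, against 11.55 at a nominal 5%. Some groups hold values at the limit of the scale or repeated values near 0, and most genes were named from these arrays. The number 11.55 is therefore not a chance level. Among them, 1 was an array property, 5 were list means and 16 were genes. Her2/Neu+ 114 had a median correlation with the other arrays of 0.427, against 0.585 to 0.678 in the rest of its group. WT 60 stood highest in WT for the MHC class II list mean (0.57) and for Bglap2 (0.22), Flywch2 (0.13), Rtl8a (0.80) and Slc22a23 (3.20). WT 54 stood highest for Psmb7 (-0.048). IFNAR1-/- 42 stood highest for Aox1 (5.47), and IFNAR1-/- 41 stood lowest for Fn1 (-3.25), Ifnar2 (-1.03) and Krt14 (-0.088). In Her2/Neu+, array 114 stood highest for Ifnar1 (3.66), array 115 highest for the list of Ifnar1 neighbours (0.45) and lowest for Lalba (5.57), and array 120 highest for Krt14 (1.79). In Her2/Neu+/IFNAR1-/-, array 103 stood lowest for the milk list (-0.45) and highest for the brown and beige fat list (1.39), and array 106 highest for the skeletal muscle list (3.17). Array 102 of that group stood lowest for Clec3b (3.46) and highest for Krt14 (0.47) and Rtl8a (0.47), and array 109 stood lowest for Glo1 (-2.90).

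The interaction test singled out Tsc22d3 (difference 2.41) and Flywch2 (difference -3.06, no measured size, since its WT and Her2/Neu+/IFNAR1-/- values were all repeated values). Both were lost with slide as a random block (adjusted p = 0.100 for each), and Tsc22d3 passed in 27 and Flywch2 in 14 of the 30 fits that left out 1 array. A different effect of receptor loss with the oncogene is thus not secure for either gene. Among the 3278 probes without a named gene, which no comparison above uses, 1 passed in IFNAR1-/- against WT, 4 in Her2/Neu+ against WT, 10 in Her2/Neu+/IFNAR1-/- against Her2/Neu+, 73 in Her2/Neu+/IFNAR1-/- against IFNAR1-/- and 2 in the interaction, with 201, 373, 530, 649 and 492 at an unadjusted p under 0.05.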

How the results depend on the processing

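The alternatives on repeated values, on the last slide and on array sets alone, and cameraPR, were chosen after seeing the data. Among named genes, lists and correlations, 0 called results turned their direction. For counts only the total was compared, and the balance of rises and falls did turn. Her2/Neu+/IFNAR1-/- against IFNAR1-/- went from 108 up and 42 down to 41 and 67 after quantile normalization. Her2/Neu+ against WT went from 13 and 2 to 12 and 26 with probes repeated on at most 3 arrays. Of the values of counts and correlations outside the fits that left out an array, 73 were the same, 15 stronger and 37 weaker. A count within 1.5 times its reported size was taken as the same. For named genes 686 kept their side and 163 became weaker. For lists, 1741 kept their side, 48 became stronger and 46 weaker. As reported, 40 of the 55 gene results and 13 of the 110 list tests were called. Only called results can become weaker, so all losses fall on these. The totals that kept their side include results never called and thus overstate how stable the called ones are. No paired analysis was possible because the groups share no replicate numbers. The base of the logarithm and the missing intensities set what could be tried: no filter on dim probes could be made, so signal over background was not examined.

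The counts below run in the order IFNAR1-/- against WT, Her2/Neu+ against WT, Her2/Neu+/IFNAR1-/- against Her2/Neu+, Her2/Neu+/IFNAR1-/- against IFNAR1-/- and interaction, and were 3, 15, 9, 150 and 2 as reported. Quantile normalization gave 24 for Her2/Neu+ against WT. The interaction count was 1 with probes that had a value on all arrays, with the array set factor or with the B cell covariate, and by limma it was 0 without the 25% of genes with the lowest SD, with array weights, with a variance trend, with array position or with repeated values missing (1103 had an unadjusted p under 0.05 as reported). With only the compared groups in the fit, which leaves fewer arrays for the spread, the counts were 6 for IFNAR1-/- against WT, 4 for Her2/Neu+/IFNAR1-/- against Her2/Neu+ and 23 for Her2/Neu+/IFNAR1-/- against IFNAR1-/-. Array weights gave 25 for IFNAR1-/- against WT, 33 for Her2/Neu+ against WT and 384 for Her2/Neu+/IFNAR1-/- against IFNAR1-/-, and array position gave 50 for the last of these. Slide as a random block (correlation 0.0951) gave 1, 3, 5, 13 and 0, and an adjusted p under 0.01, which is stricter by construction, gave 1, 3, 5, 14 and 0. With repeated values missing, which left 6454 genes, Her2/Neu+ against WT gave 38 and Her2/Neu+/IFNAR1-/- against IFNAR1-/- gave 261. Probes repeated on at most 3 arrays, which left 4871 genes, gave 1, 38, 37, 78 and 1. Without the last slide the counts were 5 for IFNAR1-/- against WT, 385 for Her2/Neu+/IFNAR1-/- against IFNAR1-/- and 1 for the interaction, a gene other than Tsc22d3 and Flywch2. Array set 1 alone gave 5, 1, 2, 2 and 0, and array set 2 alone gave 0, 745, 903, 6 and 494, where only Her2/Neu+ 114 and 119 stand for their group and the lone pair is assumed to vary like the other groups. The correlation of oncogene effects, 0.263 as reported and against a chance limit of 0.253 that was computed for that fit alone, was 0.241 with the probe of largest SD, 0.212 with array weights, 0.247 with the B cell covariate, 0.186 without the last slide, 0.156 in array set 1 and 0.148 in array set 2. Except for fewer arrays or genes and the stricter threshold, the cause was not tested. Leaving out 1 array at a time gave 3 to 5, 3 to 132, 6 to 24, 35 to 325 and 0 to 3 genes, a receptor correlation of -0.0540 to 0.0302 and an oncogene correlation of 0.194 to 0.298.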

Other observations

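The contrasts averaged over both receptor states or both backgrounds and the set of respiratory chain genes were chosen after the results had been seen. Averaged over both receptor states, the oncogene changed 295 genes, 196 up and 99 down, and 2157 had an unadjusted p under 0.05. The lists were not tested as sets in this contrast, so only single members are given. Of the 9 members of the ERBB and ERK list 3 rose, Etv5 by 2.04 ± 0.42 (SE), Dusp6 by 1.11 and Etv4 by 0.73. So did 5 of 22 cell cycle genes, Tpx2 by 1.64, Nusap1 by 1.47, Mcm2 by 1.40, Cdk1 by 1.27 and Birc5 by 1.03. Among genes named after their values were seen, Etv1, an ETS factor outside the list, rose by 2.41, Socs2, a brake on cytokine signalling, by 2.43 and Egln3, an oxygen sensor, by 2.28. Xbp1 rose by 1.19, and Derl3 and Sdf2l1, which act in protein folding in the endoplasmic reticulum, rose by 1.66 and 1.65.

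Of the 31 interferon-stimulated genes, 11 rose with the oncogene and none fell: Oas2 by 2.69, Irf7 by 2.37, Isg15 by 2.19, Ifit3 by 2.17 and Stat2 by 1.12 were among them. Of 15 luminal epithelial markers 1 passed, the epithelial adhesion gene Epcam, which rose by 2.10, and the median of the list was 0.23. Of 8 basal and myoepithelial markers 3 fell: Krt14 fell by 1.67, Tagln fell by 0.99 and Acta2 fell by 0.86 on the log2 scale. Of 15 extracellular matrix genes 4 fell, Fn1 (-1.40), Col3a1 (-1.30), Col1a1 (-0.94) and Col1a2 (-0.64). Of 11 macrophage markers 1 passed, the receptor gene Csf1r, which fell by 0.75, while the median of the list was 0.12. Hadha (-1.71), Cat (-1.45) and Idh2 (-1.32), enzymes of fat oxidation, peroxide removal and the mitochondrial matrix, fell as well and are named after their values were seen. The excess of rises turned in 2 alternatives, with 96 up and 122 down for probes repeated on at most 3 arrays and 367 up and 402 down in array set 2 alone. After quantile normalization 156 genes rose and 143 fell, 228 of the 295 passed again, and Etv4, Stat2, Tagln, Acta2 and Col1a2 were lost (adjusted p = 0.0517 to 0.154). With slide as a random block 73 of the 295 passed, among the genes named here Etv5, Etv1, Dusp6, Socs2, Egln3, Xbp1, Sdf2l1, Oas2, Isg15, Ifit3, Fn1 and Cat. The 5 cell cycle genes, the 3 basal genes, the 3 collagen genes, Etv4, Derl3, Irf7, Stat2, Epcam, Csf1r, Hadha and Idh2 were lost in that fit (adjusted p = 0.0565 to 0.120). Without the last slide 124 passed again, and the 5 cell cycle genes, Etv4, Krt14, Acta2, Col3a1, Col1a2, Csf1r, Cat and Idh2 were lost (adjusted p = 0.0578 to 0.166). With repeated values missing Etv4, Cdk1, Birc5 and Cat were lost (adjusted p = 0.0841 to 0.550). The count of 295 moved with the processing: it was 193 with the probe of largest SD, 189 with array position, 73 with slide as a random block, 183 without the last slide, 7 in array set 1 and 769 in array set 2. Left-out arrays that moved it by over 1.5 times were WT 53 (149 genes), 54 (185), 56 (155) and 57 (172), IFNAR1-/- 39 (173), 44 (155), 47 (165) and 50 (163), Her2/Neu+ 113 (169) and 119 (178), and Her2/Neu+/IFNAR1-/- 105 (184), 108 (185) and 110 (176). The highest count, 438 without Her2/Neu+ 115, lies within 1.5 times. For receptor loss the 8 genes became 16 with probes repeated on at most 3 arrays, 16 without the last slide, 3 in array set 1, 290 in array set 2, 14 without Her2/Neu+/IFNAR1-/- 110 and 16 without Her2/Neu+ 120.

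Genes of the mitochondrial respiratory chain stood lower in glands with the oncogene, averaged over both receptor states. Their mean was also lower in IFNAR1-/- than in WT glands, by -0.37. Over all genes 0 members passed the threshold there, and the set was picked from these arrays, so a fall there stays open. The set was picked after falls of its members had been seen in these arrays, was narrowed from a wider match of symbols to 79 subunit genes, and was weighed in place of the excess of rises that turned with the scaling. Tests of the set as a whole therefore say nothing about whether the pattern holds, and no p-value of it is given. The median averaged change was -0.45, against 0.07 for all genes, and 76 of 79 lay below 0. Over all genes 10 passed, all of them down: Ndufb8 (-0.98 ± 0.22 SE), Cox7a1 (-1.29), Uqcrfs1 (-1.45), Uqcrc2 (-0.73), Atp5c1 (-0.81), Ndufa10 (-1.09), Ndufa1 (-0.69), Ndufa7 (-0.70), Ndufs7 (-0.76) and Ndufc2 (-0.93). The mean of the set was 0.44 ± 0.38 (SD, n = 7) in WT, 0.08 ± 0.35 (n = 8) in IFNAR1-/-, -0.33 ± 0.61 (n = 6) in Her2/Neu+ and -0.19 ± 0.34 (n = 9) in Her2/Neu+/IFNAR1-/- glands. Its median change was -0.70 in Her2/Neu+ against WT and -0.21 in Her2/Neu+/IFNAR1-/- against IFNAR1-/-. The first of these compares groups with an intact receptor, so the state of the receptor does not account for it. In the second the means of the set differed by -0.27, with 8 of 9 arrays below the IFNAR1-/- mean. In both, 0 members passed over all genes, so whether the set fell in either one alone stays open. Whether the 2 changes differ was not tested. Loss of the receptor gave -0.42 without the oncogene, with 7 of 8 arrays below the WT mean, and 0.12 with it. In these 4 comparisons 0 members passed over all genes by limma, and 46, 7, 14 and 7 had an unadjusted p under 0.05.

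The 10 calls of respiratory chain genes depended on the fit: 1 passed with slide as a random block, Ndufb8, 2 without the last slide, 3 with the adipocyte, brown and beige fat and skeletal muscle list means as covariates, and 29 in array set 2 alone. In array set 1 alone 0 passed by limma. Leaving out 1 array gave 4 without WT 56, 5 without WT 53 or IFNAR1-/- 47 or 50, 6 without WT 54, IFNAR1-/- 39 or 44, Her2/Neu+ 113 or 119 or Her2/Neu+/IFNAR1-/- 108, and 25 without Her2/Neu+ 115. The median was -0.49 after quantile normalization and -0.46 with repeated values missing, which argues against the scaling and against repeated values as the whole cause. With the fat and muscle covariates the median was -0.30, so less fat and muscle tissue may account for part of the change. This argues against less of these tissues as the whole cause only as far as the list means follow them. Of the 4 measured genes of the brown and beige fat list, Cox7a1 and Cox8b belong to the respiratory set itself. The median was -0.47 with slide as a random block, -0.39 without the last slide, -0.35 in array set 1 and -0.66 in array set 2, and it ran from -0.55 to -0.39 with 1 array left out. No inferred slide holds both Her2/Neu+ and WT arrays, so the lower values in Her2/Neu+ against WT cannot be told apart from a difference between slides.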
